A study of Mus musculus with 6 samples.

How the data were processed

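Gene expression was measured with Affymetrix whole-genome mouse arrays on total RNA (2 ug per array) from whole liver, collected 18 hours after partial hepatectomy. The 6 arrays form 2 groups of 3, named A, B and C in each group. Cre plus livers came from mice with floxed Socs3 and a Cre recombinase transgene under the albumin promoter, which excises Socs3 in hepatocytes. Cre minus livers came from littermates with floxed Socs3 and no Cre. The labels give each array its own title and do not say that each comes from a separate mouse, and the design text gives 3 to 6 mice per genotype and time point. The p-values therefore measure the spread between these samples, which may be partly technical.

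The deposited values are on a log2 scale per the labels and the range of the values, and were made with GCRMA (version not given in the sources used here), per the submitters' processing notes. GCRMA subtracts a background estimated from probe sequence, normalizes the arrays to a common distribution and summarises each probe set. The sorted values of the arrays differed from their mean by at most 0.102, and the arrays' medians lay between 2.98 and 3.02 on the log2 scale. Values near the bottom of the scale carry little signal over background, and their fold changes are compressed. The highest value in the table was 15.7. Array data have no read depth, and the number of arrays limits the precision.

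The table holds 45101 probe sets, 64 of them control probe sets, which were left out of the tests. Gene symbols came from the platform annotation supplied with the values, updated through the Entrez ID against a RefSeq gene table of GRCm38.p6. Of the probe sets, 34958 were paired with 1 symbol, 932 with several and 9211 with none here. The Entrez ID of 34754 of the single-symbol probe sets was in the gene table, and 0 symbols changed. Probe sets with several symbols or none were not named. Probe sets with a log2 value over 4 in at least 3 of the 6 arrays were kept, which left 15563. A gene was read from its kept single-symbol probe set with the highest mean over all 6 arrays, which gave 8554 genes.

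Cre plus was compared with Cre minus with limma (version 3.58.1, R 4.3.3), using lmFit and eBayes on the log2 values with no block, two-sided, and Benjamini-Hochberg adjustment over the genes tested. All adjusted p-values for single genes are limma's unless another tool is named. Each Socs3 probe set was tested in a fit over all kept probe sets and the Socs3 probe set that missed the filter, with its p adjusted over the 3 Socs3 probe sets, and with an exact permutation test, which cannot give a p under 0.1 with 3 arrays against 3. Values are given as mean ± SD with n = 3 per group, and log2 fold changes as Cre plus minus Cre minus with limma's standard error.

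A set of 37 gene lists (966 different genes) was fixed from textbook knowledge of liver and cytokine signalling before the data were examined. Of these genes, 886 had a single-symbol probe set and 623 were kept. The other listed genes were not analysed here. The 31 lists with at least 5 kept members were tested with camera in limma at its preset inter-gene correlation of 0.01, with adjustment over the lists. Camera was also run with the correlation estimated for each list, and fry was run as another tool. Fry's main p asks whether a list's members move on balance in 1 direction, and its mixed p asks whether they change in either direction. Neither compares the list with other genes.

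The genes named in the text follow a rule that was also set before the data were examined. It takes Socs3, then up to 15 genes with the largest rise and 15 with the largest fall among those past an adjusted p under 0.05 whose groups do not overlap. For each list it takes up to 4 members past the threshold, filled up to 2 by smallest p. Where fewer than 10 genes pass in a direction, it adds those with the smallest p up to 10, which did not pass. Of the 85 genes named this way, 33 had more than 1 kept probe set, and in 4 of them (Stx6, Rgs5, Nolc1 and Fmo2) the probe sets had fold changes of opposite sign. Genes outside this rule are said to have been chosen after their values were seen.

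The alternatives were arrays shifted to a common median, quantile normalization, no filter, a filter at a log2 value over 6, a prior with an intensity trend and robust estimation, the mean of all probe sets of a gene, probe sets without the _x_at and _s_at kinds, every kept probe set tested, a replicate block, each array left out in turn, array weights, an added 2-fold minimum, and the other list tests. A threshold of adjusted p under 0.10 was added after the data were seen. The fits were tested on 20 simulated sets of the same 8554 genes and arrays, each with 200 genes changed. For Cre plus against Cre minus, limma recovered 50.9% of genes changed by 0.5 on the log2 scale, 92.8% of those changed by 1 and 99.4% of those changed by 2, and 4.99% of its calls were false. In the same 20 sets with the STAT3 target list shifted by 0.5, camera with either correlation and fry called that list in 20. Other lists, some of which share members with it, were called 7 times by camera with the preset correlation, 0 times with the estimated correlation and 8 times by fry. The simulated genes varied independently of each other, which the genes of a liver do not. They were also drawn with the same SD in both groups. In the real data the root mean square SD over the genes was 0.16 in Cre minus and 0.24 in Cre plus. The shares recovered therefore hold for such simulated sets and may be lower in the real data.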

Results

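The data compare liver gene expression 18 hours after partial hepatectomy, the surgical removal of most of the liver, in mice that lack Socs3 in hepatocytes (Cre plus, n = 3 arrays) and in littermates that keep it (Cre minus, n = 3 arrays). Socs3 encodes a feedback inhibitor of cytokine signalling through JAK kinases and STAT3. The design compares the regenerating liver with and without Socs3 in hepatocytes, at 18 hours only. With no array from before surgery, a difference present before it cannot be told apart from an altered response to it. The Cre minus littermates carry no Cre, so an effect of Cre itself cannot be told apart either. Correlations between arrays over the 8554 genes tested were 0.995 within Cre minus, 0.987 to 0.990 within Cre plus and 0.982 to 0.993 between the groups. Cre plus B stood apart, with correlations of 0.991 to 0.993 with the Cre minus arrays and of 0.989 with Cre plus A and 0.987 with Cre plus C. Of the genes tested, 63.1% had a larger SD in Cre plus than in Cre minus. All 6 livers had the profile of males, with the Y-linked Eif2s3y between 8.74 and 9.25 and Xist, which is expressed from the inactive X chromosome of females, between 2.81 and 2.87 on the log2 scale.

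Socs3 was lower in every Cre plus liver than in any Cre minus liver on all 3 of its probe sets. On the brightest probe set the log2 values were 9.09, 9.30 and 9.24 in Cre minus A, B and C and 7.44, 6.69 and 7.47 in Cre plus A, B and C. The log2 fold change was -2.01 ± 0.22 (SE), so the Cre plus signal was 24.9% of the Cre minus signal (95% interval 17.0% to 36.5%). On the next brightest the values were 8.37, 9.07 and 8.78 against 7.37, 6.91 and 7.15, a log2 fold change of -1.60 ± 0.21. The third probe set lay near background, at 4.45, 3.81 and 3.84 against 3.02, 3.37 and 3.45, and missed the filter. Adjusted over the 3 probe sets, limma's p was 4.02e-04, 4.60e-04 and 0.0123 in that order, and the fall passed on each. With limma's adjustment over all genes, the Socs3 gene had an adjusted p = 0.0732 and did not pass. The exact permutation p was 0.1 for each probe set, the smallest that 3 against 3 can give. The brighter probe sets are of the _x_at kind, which can bind related transcripts. RNA from whole liver includes cells in which Cre is not expressed, and whether the probe sets lie in the excised part is not given in the sources used here.

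**Figure D1:**
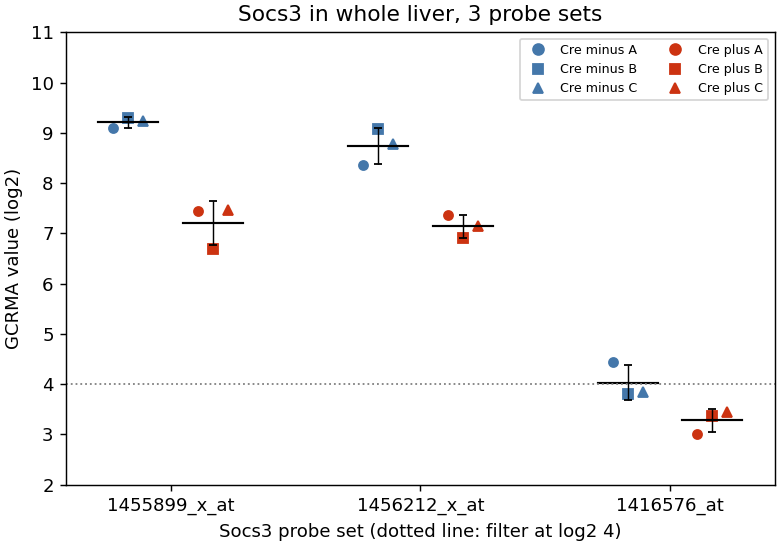
Socs3 in each liver. The y axis gives the deposited log2 value and the x axis the 3 Socs3 probe sets; points are single arrays, black bars are group means and error bars are SD (n = 3). Cre plus values lie below Cre minus values on each probe set, at 6.69 to 7.47 against 9.09 to 9.30 on the brightest.

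Tifa and Steap4 rose in Cre plus livers. Tifa, an adaptor protein that links TRAF6 to NF-kB activation, rose 3.81-fold, from 8.72 ± 0.05 to 10.64 ± 0.14 (log2, SD, n = 3), a log2 fold change of 1.93 ± 0.09 with limma's adjusted p = 0.00516. Steap4, a metalloreductase induced by IL-6 and STAT3, rose 2.38-fold, from 12.01 ± 0.12 to 13.26 ± 0.10, a log2 fold change of 1.25 ± 0.09 with adjusted p = 0.0417. Both were higher in 3 of 3 Cre plus livers than in any Cre minus liver. These were the 2 of 8554 genes past an adjusted p under 0.05, and 0 lower genes passed. At an unadjusted p under 0.05 limma listed 566 higher and 702 lower genes, 1268 in all, where 428 would be listed by chance. The groups did not overlap in 21.2% of genes, against 10% by chance.

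The next genes by p did not pass over all genes and are given as values. Among higher genes these were Slc13a5, the citrate transporter of the hepatocyte membrane, with a log2 fold change of 1.85 ± 0.17, Ugt2b38 with 2.29 ± 0.26, Gas6, a ligand of the TAM receptors, with 1.12 ± 0.13, Raph1 with 0.92 ± 0.10, Stx6 with 0.82 ± 0.09, Snx10 with 0.73 ± 0.08, Fndc3b with 0.59 ± 0.07 and Garem1 with 0.58 ± 0.06. Slc13a5 lay near the filter in Cre minus, at 4.52, and its 2 kept probe sets gave 1.85 and 2.28. The value for Stx6 depends on its probe set, since it was 0.27 with the mean of its 4 kept probe sets and 0.22 without the _x_at and _s_at kinds. Among lower genes, beside Socs3, were the drug-metabolizing enzymes Fmo1 (-1.24 ± 0.14) and Cyp3a25 (-1.21 ± 0.14) and the prostaglandin-degrading enzyme Hpgd (-1.12 ± 0.13). Vnn3 (-0.74 ± 0.10), Igfbp2 (-0.70 ± 0.08), Hsd17b13 (-0.61 ± 0.08), Slc25a22 (-0.52 ± 0.06), Pnpla7 (-0.48 ± 0.05) and Ugp2 (-0.46 ± 0.06) followed. The count of genes past the threshold depended on single arrays and on the filter. It was 0 without Cre minus A, without Cre minus B or without Cre minus C, 1 (Tifa) without Cre plus A, 13 without Cre plus B, 2 (Tifa and Slc13a5) without Cre plus C, 0 with no filter and 56 (38 higher and 18 lower, Tifa, Steap4 and Socs3 among them) with the filter at a log2 value over 6.

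**Figure D2:**
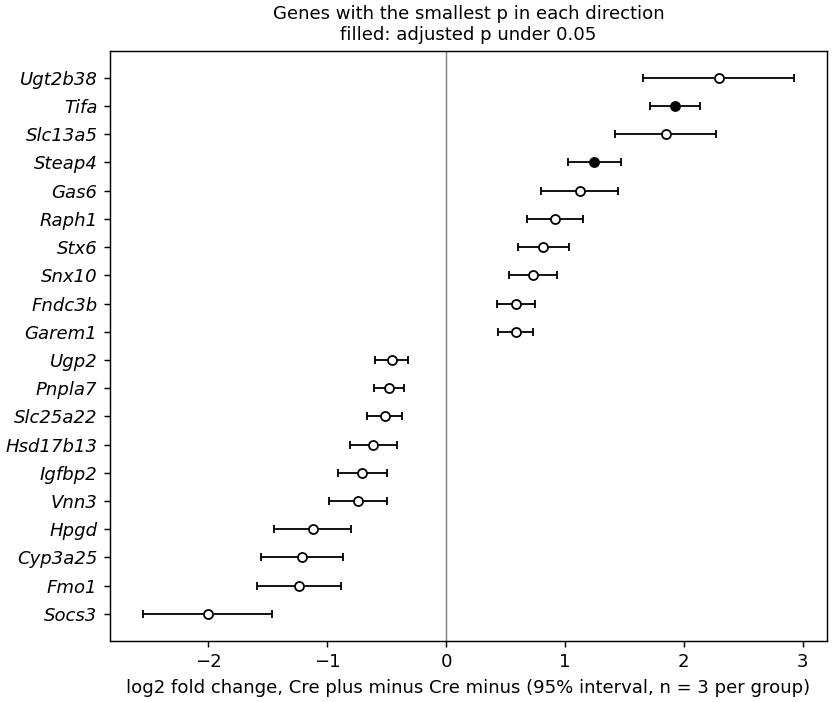
Genes named by smallest p in each direction. The x axis gives the log2 fold change, Cre plus minus Cre minus, and the y axis the gene; points are estimates and bars limma's 95% intervals (n = 3 per group). Filled points, Tifa at 1.93 and Steap4 at 1.25, passed an adjusted p under 0.05 and open points, Socs3 at -2.01 among them, did not.

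Genes that respond to IL-6 family cytokines were higher together. Target genes of STAT3, the transcription factor that Socs3 restrains, rose as a list in Cre plus, with a median log2 fold change of 0.48 (camera adjusted p = 3.44e-08). The call was lost at adjusted p = 0.0511 with an estimated correlation, and fry gave 0.00169. Of 23 measured members, 21 had higher and 2 lower values. Over all genes 0 passed, at an unadjusted p under 0.05 12 were higher and 1 lower, and adjusted over the list alone 12 higher and 1 lower passed and 10 did not. The examples by smallest p were Cebpb, a transcription factor of the acute phase response, at 0.51 ± 0.07 and Stat3 itself at 0.52 ± 0.08. The lower gene was Ccnd1, which encodes cyclin D1 and promotes entry into the cell cycle, at -0.67 ± 0.14.

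Genes of positive acute phase proteins, most of which the liver secretes during inflammation, also rose as a list (camera adjusted p = 3.12e-07). The call was lost at adjusted p = 0.0511 with an estimated correlation, and fry gave 0.00169. All 29 measured members had higher values, with a median of 0.07 and a mean of 0.39. Over all genes 1, Steap4, passed, at an unadjusted p under 0.05 7 were higher, and adjusted over the list alone 5 passed and 24 did not. A2m, a protease inhibitor, had 1.30 ± 0.17. It passed adjusted over the list alone, as did Steap4, Mt1 (0.46 ± 0.10), Mt2 (0.79 ± 0.16) and Serpina10 (0.42 ± 0.09). Of these, Steap4, Mt1 and Mt2 are not secreted proteins. The mean of the list includes Cd14 at 3.66 ± 1.62. Mt1, Mt2, Serpina10 and Cd14 were chosen after their values were seen. The 17 members with a mean log2 value over 14, near the top of the scale, had a median of 0.05, and the 12 dimmer members a median of 0.52. Among all 58 genes tested over that level, these members included, 35 were higher and the median was 0.02. Components of the IL-6 family signalling pathway did not pass as a list (median 0.08, adjusted p = 0.0944, fry 0.103, passing in 3 of 16 alternatives, at 0.0270 without Cre minus C, 0.0202 with no filter and 0.0174 with the filter at a log2 value over 6), with 15 of 23 members higher and 8 lower. Over all genes 0 passed, and adjusted over the list alone 3 higher members passed, Stat3, Ptpn1, a phosphatase that opposes cytokine receptor signalling (0.72 ± 0.11), and Osmr, a receptor subunit for oncostatin M (1.05 ± 0.16). Osmr was chosen after its values were seen.

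Immediate early genes, which respond within minutes to growth factors, cytokines or stress, rose as a list (median 0.46, camera adjusted p = 8.11e-07). Their call was lost at adjusted p = 0.416 with an estimated correlation, and fry gave 0.103. Of 19 measured members 17 were higher and 2 lower in value, with 0 past the threshold over all genes, 9 higher at an unadjusted p under 0.05, and 6 higher past it and 13 not past it adjusted over the list alone. The AP-1 subunits Junb (0.80 ± 0.14) and Jund (0.45 ± 0.10) had the smallest p. The Cre plus livers differed among themselves here, since the mean of the members lay above the Cre minus mean by 0.98 in Cre plus A, 0.23 in Cre plus B and 1.07 in Cre plus C.

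The list of NF-kB targets and inflammatory genes rose as well (median 0.30, camera adjusted p = 0.00209), a call lost at adjusted p = 0.416 with an estimated correlation and at 0.103 by fry. The mean shift was 0.65 in Cre plus A, 0.18 in Cre plus B and 0.25 in Cre plus C, and went from 0.36 to 0.22 without Cre plus A. Of its 13 measured members 11 were higher and 2 lower in value. No member passed over all genes, 4 were higher at an unadjusted p under 0.05, and adjusted over the list alone 3 higher members passed and 10 did not, with Il1r1, the IL-1 receptor, at 0.82 ± 0.14 and the neutrophil chemokine Cxcl1 at 1.07 ± 0.21. Interferon-stimulated genes rose as a list (median 0.17, camera adjusted p = 8.32e-05), which was lost at adjusted p = 0.416 with an estimated correlation and at 0.309 by fry. Among 36 measured members 30 were higher and 6 lower in value. None passed over all genes, 7 were higher and 1 lower at an unadjusted p under 0.05, and adjusted over the list alone 3 higher members passed and 33 did not. Examples were the nucleic acid sensor Zbp1 (0.95 ± 0.20) and the immunoproteasome subunit Psmb10 (0.65 ± 0.11). The mean shift of this list was 0.73 in Cre plus A, 0.14 in Cre plus B and 0.14 in Cre plus C, and went from 0.33 to 0.14 without Cre plus A.

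Ribosome biogenesis and MYC target genes rose as a list by a small amount (median 0.15, camera adjusted p = 1.59e-04), and the call was lost at adjusted p = 0.416 with an estimated correlation and at 0.297 by fry. Of 36 measured members 29 were higher and 7 lower in value, with 0 past the threshold over all genes, 6 higher at an unadjusted p under 0.05, and 0 past it adjusted over the list alone. The ribosomal RNA processing factor Utp20 had 0.29 ± 0.08 and Nolc1 0.42 ± 0.13, and the kept probe sets of Nolc1 had fold changes from -0.10 to 0.42. Mean shifts were 0.21 in Cre plus A, -0.02 in Cre plus B and 0.32 in Cre plus C, and the mean over all 3, 0.17, became 0.26 without Cre plus B and 0.10 without Cre plus C.

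**Figure D3:**
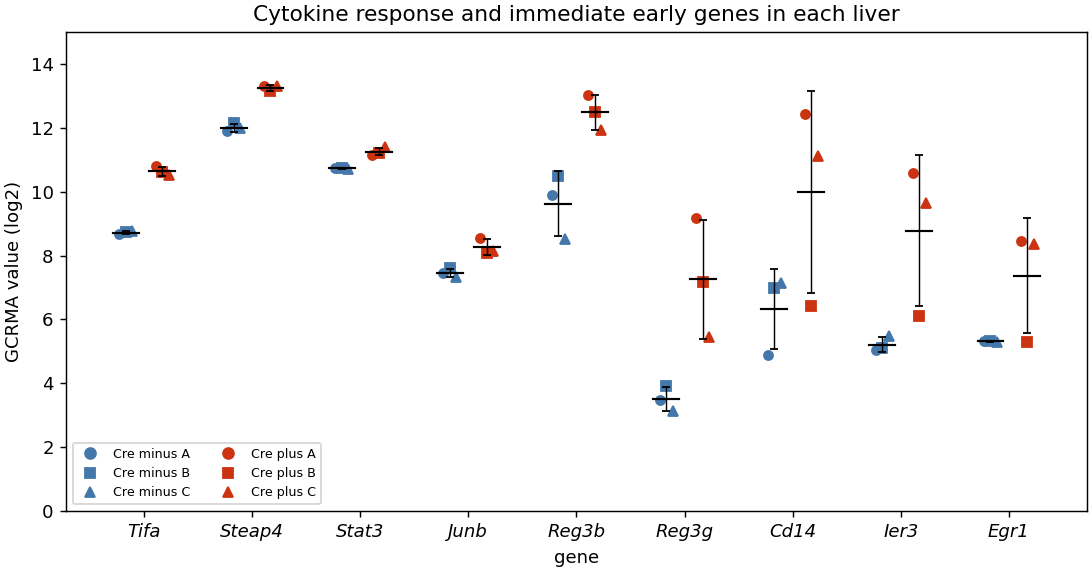
Cytokine response and immediate early genes in each liver. The y axis gives the log2 value and the x axis the gene; points are single arrays, black bars are group means and error bars are SD (n = 3). Tifa and Steap4 lie apart between the groups in every liver, while Egr1 in Cre plus B, at 5.28, lies at the level of the Cre minus livers (5.28 to 5.33); genes other than Tifa, Steap4, Stat3 and Junb were chosen after their values were seen.

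Several lists of metabolic genes, among them fatty acid oxidation and bile acid synthesis, had lower values in Cre plus livers, while most sterol synthesis genes did not. Fatty acid oxidation and PPARa target genes fell as a list (median -0.25, camera adjusted p = 2.69e-07), a call lost at adjusted p = 0.416 with an estimated correlation and at 0.103 by fry. Cre plus B stood apart, with a mean shift of -0.59 against -0.16 in Cre plus A and -0.17 in Cre plus C, and without it the mean went from -0.31 to -0.17. Of 29 measured members 26 were lower and 3 higher in value. No single member passed over all genes, 14 were lower at an unadjusted p under 0.05, and adjusted over the list alone 2 lower members passed and 27 did not, the acyl-CoA dehydrogenase Acadm (-0.46 ± 0.07) and the pantetheinase Vnn1 (-0.90 ± 0.19). Bile acid synthesis and transport genes fell (median -0.36, camera adjusted p = 2.73e-06), which was lost at adjusted p = 0.416 with an estimated correlation and at 0.0618 by fry. In this list 21 of 23 members were lower and 2 higher. With adjustment over all genes 0 passed, 11 were lower at an unadjusted p under 0.05, and adjusted over the list alone 3 lower members passed and 20 did not, with the sterol transporter Abcg5 at -1.00 ± 0.14 and the phospholipid transporter Abcb4 at -0.71 ± 0.12.

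Xenobiotic metabolism genes fell as a list (median -0.21, camera adjusted p = 1.54e-05), a call lost at adjusted p = 0.416 with an estimated correlation and at 0.103 by fry. Fmo1 and Cyp3a25, given above, led the 29 lower of 32 measured members, and 3 were higher. Over all genes 0 passed, 10 were lower at an unadjusted p under 0.05, and adjusted over the list alone 4 lower members passed and 28 did not. Genes of gluconeogenesis, insulin response and amino acid catabolism fell (median -0.25, camera adjusted p = 0.00194), and this was lost at adjusted p = 0.416 with an estimated correlation and at 0.103 by fry. There 22 of 31 members were lower and 9 higher in value, 0 passed over all genes and 11 were lower at an unadjusted p under 0.05. Adjusted over the list alone 1 passed and 30 did not. Slc2a2, the hepatocyte glucose transporter, had -1.45 ± 0.20 and was the member that passed, and Hgd, an enzyme of tyrosine breakdown, had -0.64 ± 0.15.

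Fatty acid and triglyceride synthesis genes fell as a list (median -0.18, camera adjusted p = 0.0145), which was lost at adjusted p = 0.416 with an estimated correlation, at 0.209 by fry, at 0.284 without Cre plus B and at 0.0798 with no filter. Its mean of -0.11 became -0.07 without Cre minus A, 0.02 without Cre plus B and -0.20 without Cre plus C. Of 26 members 19 were lower and 7 higher, 0 passed over all genes or adjusted over the list alone, and 7 were lower at an unadjusted p under 0.05. The elongase Elovl5 had -0.69 ± 0.14 and the acyltransferase Gpam -0.40 ± 0.09. Negative acute phase and other hepatocyte secreted proteins fell slightly (median -0.08, camera adjusted p = 0.0183), and the call was lost at adjusted p = 0.626 with an estimated correlation, at 0.264 by fry, at 0.0696 without Cre minus A and at 0.219 without Cre plus A. Its mean of -0.08 became -0.04 without Cre minus A, -0.03 without Cre plus A, -0.05 without Cre plus B and -0.15 without Cre plus C. Of 23 members 19 were lower and 4 higher, 0 passed over all genes or adjusted over the list alone, and 4 were lower at an unadjusted p under 0.05. The retinol carrier Rbp4 had -0.40 ± 0.09 and fetuin-A (Ahsg) -0.27 ± 0.08.

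Markers of other liver cell types moved beside these groups. Kupffer cell and macrophage markers fell as a list (median -0.29, mean -0.10, camera adjusted p = 4.69e-05), a call lost at adjusted p = 0.175 with an estimated correlation, while fry gave 0.0192. The mean became -0.20 without Cre plus A and -0.02 without Cre plus B, since the mean shifts were 0.09 in Cre plus A, -0.27 in Cre plus B and -0.13 in Cre plus C. Of 21 measured members 19 were lower and 2 higher, Mpeg1 and Cd14. Over all genes 0 passed, 9 were lower and 1 higher at an unadjusted p under 0.05, and adjusted over the list alone 8 lower members passed and 13 did not. The signalling adaptor Tyrobp had -0.41 ± 0.07 and the complement component C1qa -0.39 ± 0.07. Sinusoidal endothelial markers fell as a list (median -0.17, camera adjusted p = 0.00194), which was lost at adjusted p = 0.416 with an estimated correlation and at 0.209 by fry. Their mean of -0.13 became -0.08 without Cre plus C. Of 21 members 17 were lower and 4 higher, 0 passed over all genes, 6 were lower at an unadjusted p under 0.05, and adjusted over the list alone 1 passed and 20 did not. The member that passed was the Fc receptor Fcgr2b (-0.54 ± 0.09), and the phosphatase Ptprb had -0.27 ± 0.08.

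Other cell type lists did not pass. Stellate cell and fibroblast markers had a median of 0.05 (adjusted p = 0.234, passing at 0.0274 with no filter), with 11 of 19 members higher, 8 lower and 0 past the threshold over all genes or adjusted over the list alone. Pdgfra had 0.47 ± 0.16 and Rgs5 0.50 ± 0.11, with Rgs5 probe sets in opposite directions. Bile duct cell markers had a median of 0.45 (adjusted p = 0.0522), which passed in 8 of 15 alternatives, among them 0.0426 without Cre minus C, 0.00774 without Cre plus B, 0.0409 with a common median, 0.0346 with array weights and 0.0225 with the mean of probe sets, with 6 of 7 members higher and 1 lower, 0 past the threshold over all genes and 1 adjusted over the list alone. The leading members, Krt18 (0.53 ± 0.13) and Krt8 (0.45 ± 0.18), are keratins of hepatocytes too. Lists with fewer than 5 kept members were not tested. B and plasma cell markers had 4 (Cd74 at -0.50 ± 0.14 and H2-Ab1 at -0.13 ± 0.07), neutrophil markers 4 (Lcn2 at 0.07 ± 0.05 and Il1b at 0.48 ± 0.47), sex chromosome genes 3 (Uty at 0.17 ± 0.17 and Eif2s3y at 0.14 ± 0.14), erythroid markers 2 (Tfrc at -0.46 ± 0.44 and Alas2 at 0.03 ± 0.12), pancreas and fat markers 1 (Car3 at 0.36 ± 0.35), and T and NK cell markers 0. No member of these lists passed over all genes or adjusted over its list alone. The mean shift of the neutrophil markers was 1.17 in Cre plus A, -0.12 in Cre plus B and 0.01 in Cre plus C.

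Genes of the cell cycle did not pass as lists in a single direction. For DNA replication and G1/S genes the median log2 fold change was -0.02, the mean -0.01 and the camera direction upward (adjusted p = 0.948), so that median and test differed in sign. Of 57 genes of this list on the array, 31 were kept. The mean value of these 31 members was 6.15 ± 0.09 in Cre minus and 6.14 ± 0.07 in Cre plus (SD, n = 3, exact permutation p = 1). Of the members 12 were higher and 19 lower in value, 0 passed over all genes or adjusted over the list alone, and 1 was higher at an unadjusted p under 0.05. Ung, a DNA repair glycosylase, had 0.49 ± 0.16 and Dbf4, an activator of replication origins, 0.20 ± 0.09. Of 49 mitosis and G2/M genes on the array, 9 passed the filter (median -0.08, adjusted p = 0.404, 3 higher and 6 lower, 0 past the threshold), with Cks2 at -0.33 ± 0.10 and Cks1b at 0.22 ± 0.06. G1 cyclins, CDKs and CDK inhibitors had a median of -0.01 (adjusted p = 0.510), with 6 of 15 members higher and 9 lower. Of these 0 passed over all genes and 1 adjusted over the list alone, Ccnd1, followed by Ccnd3 at -0.27 ± 0.07.

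The remaining lists did not pass, and 0 of their members passed over all genes. Sterol synthesis genes had a median of 0.12 (adjusted p = 0.0873), passing in 4 of 16 alternatives, at 2.69e-04 without Cre plus C, 0.00279 with no filter, 0.0123 with array weights and 0.0475 with quantile normalization, with Insig1 at 0.23 ± 0.08 and Nsdhl at 0.30 ± 0.10. For p53 target genes it was 0.11 (adjusted p = 0.112, passing at 0.0305 without Cre plus B and 0.0454 with no filter), with Ei24 at -0.28 ± 0.09 and Ccng1 at 0.36 ± 0.11. Hepatocyte transcription factors had -0.09 (adjusted p = 0.181), with the xenobiotic receptor Nr1i3 at -0.76 ± 0.12 and Foxa1 at -0.29 ± 0.10. Female-biased liver genes had -0.16 (adjusted p = 0.185), with Cyp4a14 at -1.32 ± 0.34 and Fmo2 at -0.11 ± 0.09, whose probe sets moved in opposite directions. Apoptosis regulators had 0.05 (adjusted p = 0.185), with Tnfrsf1a at 0.31 ± 0.08 and Birc2 at 0.28 ± 0.11. Complement and coagulation genes had -0.04 (adjusted p = 0.190, passing at 0.0495 without Cre minus C and 0.00497 without Cre plus B), with Klkb1 at -1.13 ± 0.22 and C8g at -0.22 ± 0.06.

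ERK feedback and target genes had a median of 0.11 (adjusted p = 0.545), led by Ccnd1 and by the ERK phosphatase Dusp6 at -0.67 ± 0.20, so that its leading members were lower. Growth hormone and STAT5 targets had -0.04 (adjusted p = 0.585), with Nrn1 at -0.88 ± 0.23 and Elovl3 at -1.11 ± 0.30. Unfolded protein response genes had 0.01 (adjusted p = 0.682), with Xbp1 at 0.49 ± 0.09 and Pdia4 at -0.17 ± 0.07. Fetal liver and progenitor genes had a median of -0.03, a mean of 0.14 and a downward camera direction (adjusted p = 0.948), so that mean and test differed in sign, with Cdh1 at -0.24 ± 0.08 and Sox9 at 0.38 ± 0.23. Growth factors and their receptors had 0.04 (adjusted p = 0.976), with Igfbp2 as given above and Fgf1 at -0.53 ± 0.16. Adjusted over the list alone, 1 member passed in each of the lists of hepatocyte transcription factors (Nr1i3), ERK targets (Ccnd1), unfolded protein response (Xbp1) and growth factors (Igfbp2), and 0 in the other lists of this and the preceding paragraph.

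In all, 14 of 31 lists passed with the preset correlation, 6 higher and 8 lower. With an estimated correlation 0 passed, and 3 had an unadjusted p under 0.05. The estimated correlation was over the preset 0.01 in 24 of 31 lists and in 12 of the 14 that passed, and where members are correlated more than the preset assumes its p is too small. The STAT3 targets and the acute phase proteins were not among those 12, with estimates of -0.029 and -0.016. A correlation over the preset therefore does not account for the loss of their calls, and for the other 12 it may not be the only reason. What else lowers the calls with an estimated correlation was not tested. By fry 3 passed, the STAT3 targets, the acute phase proteins and the macrophage markers. By fry's mixed p, which asks for change in either direction, 16 passed. They include lists that did not pass with camera, mitosis (0.00310), G1 cyclins (0.0112), growth factors (0.00198), IL-6 components (0.00240) and ERK targets (0.0220). The exact permutation p of the list mean was 0.6 for fatty acid and triglyceride synthesis, 0.5 for negative acute phase proteins and 0.4 for macrophage markers. It was 0.3 for ribosome biogenesis and 0.2 for fatty acid oxidation. In these lists the arrays' means overlapped between the groups. It was 0.1, the smallest possible, for the other lists that passed camera.

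**Figure D4:**
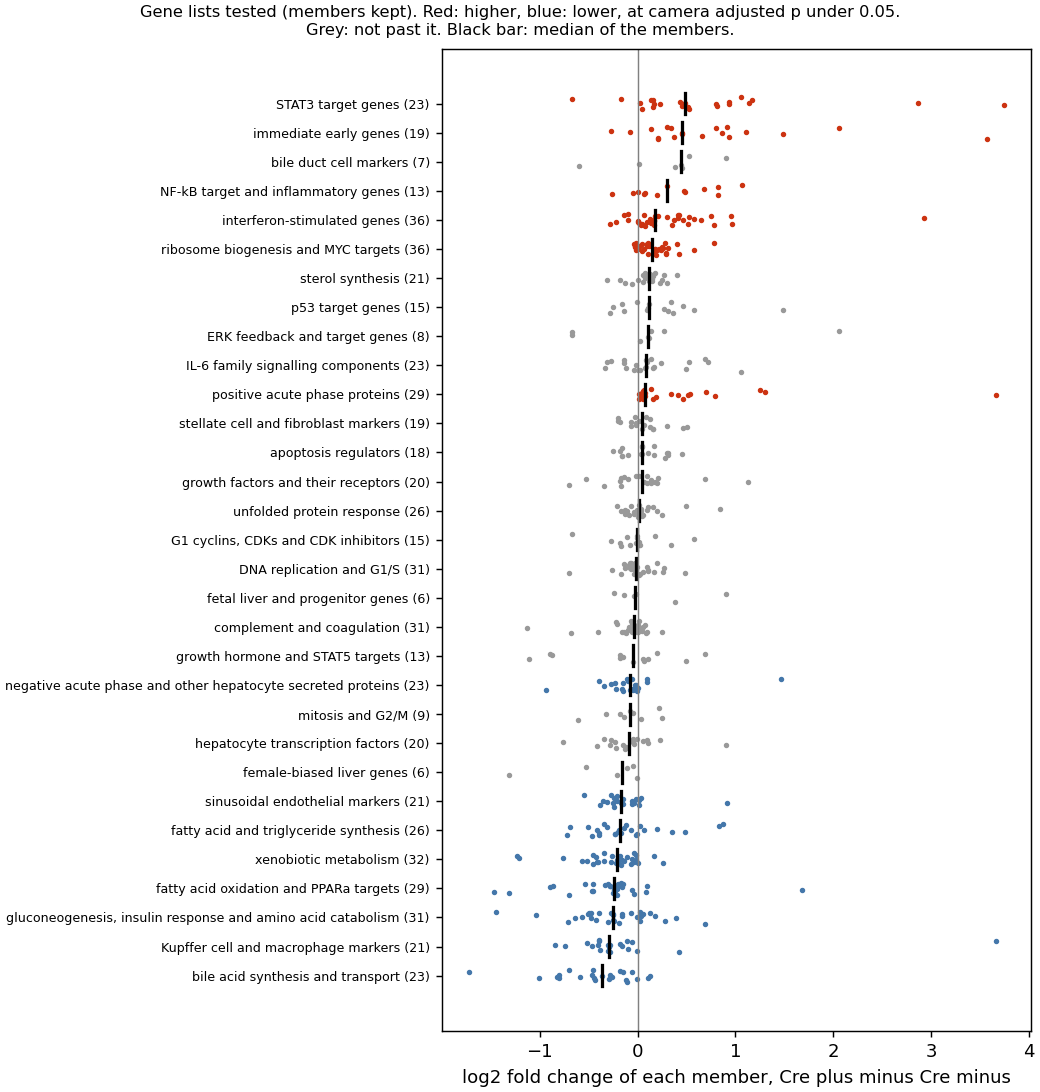
Members of the 31 gene lists tested. The x axis gives each kept member's log2 fold change, Cre plus minus Cre minus, and the y axis the list with its number of members; points are genes and black bars medians. Red and blue lists passed camera with the preset correlation, higher or lower, with medians from -0.36 for bile acid genes to 0.48 for STAT3 targets.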

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

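The alternatives were fixed before the data were examined, except the threshold of adjusted p under 0.10, which was chosen after seeing the data and gave 74 genes (46 higher, 28 lower). The number of genes past an adjusted p under 0.05 was 2 with limma, 0 with no filter on dim probe sets, where 18193 genes were tested, and 56 with a log2 value over 6 in at least 3 arrays, where 6236 were tested. Leaving out an array each gave 0 to 13 genes. It was 0 without Cre minus A, B or C, 1 without Cre plus A, 13 without Cre plus B and 2 without Cre plus C. The letters A, B and C are shared by the groups, but same-letter arrays did not deviate together (correlations of -0.15, -0.10 and 0.02 for A, B and C, and 0 of 6 arrays correlated best with its own letter), and with the replicate block 0 genes passed. The adjusted p ran from 9.36e-04 to 0.208 for Tifa and from 0.00956 to 0.283 for Steap4 over the alternatives, with log2 fold changes of 1.85 to 1.99 and 1.19 to 1.43. Socs3 kept its direction and stayed past the threshold over its probe sets in every alternative run, from -2.14 to -1.75 with an array left out. The number of lists was 13 to 17 in the alternatives with the preset correlation, 0 with the correlation estimated and 3 by fry. Why these counts moved was not tested, apart from the numbers of genes and arrays that the settings leave.

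The direction of a test reversed only for results that had not passed, although the mean of the fatty acid and triglyceride synthesis list, which had passed, turned from -0.11 to 0.02 without Cre plus B. For the growth factor list the adjusted p was then 0.978 with no filter, 0.906 with a log2 value over 6, 0.80 with the mean of probe sets, 0.974, 0.933 and 0.547 without Cre minus A, Cre minus C and Cre plus B, 0.990 with array weights and 0.611 by fry. For DNA replication and G1/S it was 0.930 with quantile normalization, 0.975 with a log2 value over 6, 0.912, 0.910 and 0.906 without Cre minus B, Cre minus C and Cre plus A, and 0.935 by fry. For fetal liver genes it was 0.965 with a common median, 0.316 with no filter, and 0.734, 0.933 and 0.674 without Cre minus C, Cre plus A and Cre plus B. The others were G1 cyclins (0.768) and growth hormone targets (0.877) with no filter, ERK targets (0.639) with a log2 value over 6, the unfolded protein response (0.905) without Cre minus B, and complement (0.688), sterol synthesis (0.906) and growth hormone targets (0.811) without Cre plus A. Among named genes, log2 fold changes reversed to -0.0024 for Eif2s3y and -0.019 for Alas2 without Cre minus C, -0.086 for Il1b without Cre plus A, 0.020 for Tfrc and -0.079 for Alas2 without Cre plus B, and -0.039 for Car3 without Cre plus C. With an array left out, adjusted p ran from 0.00497 to 0.875 for complement, 0.436 to 0.912 for DNA replication, 0.322 to 0.905 for the unfolded protein response, 2.69e-04 to 0.906 for sterol synthesis, 0.528 to 0.933 for fetal liver genes and 0.145 to 0.875 for growth hormone targets. The log2 fold change ran from -0.83 to 0.020 for Tfrc, -0.086 to 0.76 for Il1b, -0.039 to 0.61 for Car3, -0.0024 to 0.22 for Eif2s3y and -0.079 to 0.14 for Alas2. The cause was not tested. Low signal over background limits genes near a log2 value of 4. Brightness near the top of the scale may limit the most abundant acute phase transcripts, which was not told apart from a smaller change.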

Other observations

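All tests in this part were chosen after the results were seen. The genes named here were chosen after their values were seen as well, except those the report already names.

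The antimicrobial lectins Reg3b and Reg3g, both STAT3 targets, had higher values in each Cre plus liver than in any Cre minus liver. Reg3b was at 9.63 (mean, log2) in Cre minus and 12.49 in Cre plus, a log2 fold change of 2.87 ± 0.55 (SE) with limma's adjusted p = 0.143, and Reg3g was at 3.51, near background, in Cre minus and 7.26 in Cre plus (adjusted p = 0.188). Neither passed over all genes. Cd14, a lipopolysaccharide co-receptor that sits in both the acute phase and the macrophage list, was at 12.45 in Cre plus A and 11.11 in Cre plus C, but at 6.41 in Cre plus B and 4.89 to 7.13 in Cre minus. Most mitotic regulators stayed under the filter, with Mki67 at a mean of 2.91, Top2a at 3.50 and Cdk1 at 2.59 over the 6 livers. Of 57 DNA replication and G1/S genes on the array, 31 passed the filter. Pcna was at 9.58 in Cre minus with a log2 fold change of -0.07, but Tk1 (2.02), Tyms (2.90) and Mcm2 (3.90) stayed under the filter. The result for that list covers its kept members only.

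Grouping was examined over the 10 ways to split the 6 arrays into groups of 3. The real split gave 2 genes past an adjusted p under 0.05 and the highest other split 0, and 1 split, the real one, gave as many. It gave 14 lists with camera's preset correlation, the highest other split 11 and the other splits a median of 8, and 1 split gave as many. Camera at the preset correlation thus called many lists under other groupings too. Each other split sets 2 arrays of 1 group and 1 of the other against the rest, so part of a difference between the groups stays in it. Differences between single livers stay as well. Camera's p-values may be too small here, but these splits cannot show whether they are. With 10 splits a share under 0.05 cannot be reached. By fry the real split gave 3 lists and the highest other 0, and at an unadjusted p under 0.05 it gave 1268 genes and the highest other 580.

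The lower metabolic lists may reflect the genotype or a technical cause. A smaller share of hepatocyte RNA would raise the markers of every other cell type, if those cells were otherwise unchanged. Macrophage and sinusoidal endothelial markers that no other fixed list holds were lower instead, by a mean log2 shift of -0.22 ± 0.05 (SE over arrays), which argues against that cause as the only one. A smaller share would also lower hepatocyte genes of other lists, if those genes were otherwise unchanged. Complement and coagulation genes had a median of -0.04, with 22 of 31 members lower and 9 higher, and all 29 acute phase members were higher. No test compared these lists with the metabolic ones. A smaller hepatocyte share together with a change in the macrophages and endothelial cells therefore stays open. Stellate markers, at 0.07 ± 0.06, and bile duct markers, at 0.17 ± 0.16, were within 3 standard errors of 0. The test was first made with all members of both lists, Cd14 included, and was narrowed to these markers and to 3 standard errors after that value, -0.12 ± 0.05, was seen, so it rests on a choice made with the result in view. A scaling that lowers most genes of the Cre plus arrays cannot be told apart from other causes here. The median log2 fold change of the genes outside these lists was -0.0065 ± 0.0132 against -0.21 for the members, but GCRMA had already brought the arrays to a common distribution, which holds that median near 0. A genotype effect stays open and was not tested apart from the grouping.

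For the lower macrophage and endothelial markers, a smaller share of all nonparenchymal RNA could account for the pattern if stellate cell markers fell alike. The shift of macrophage and endothelial markers minus that of the stellate markers was -0.28 ± 0.10, or -0.18 ± 0.08 with all members, which is within the 3 standard errors chosen later though not within the 2 chosen first, so this explanation cannot be told apart from a change of particular cell types with 3 arrays per group. A smaller share of macrophage RNA would lower every macrophage marker. Among the 19 markers of that list alone, 18 were lower and 1, Mpeg1 (0.42 ± 0.14), was higher at an unadjusted p under 0.05, which decides neither way. A change of expression within macrophages, in response to hepatocytes without Socs3, stays open and was not tested.

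Of the 19 immediate early genes, 13 were lowest in Cre plus B among the Cre plus livers and 6, Jun, Jund, Btg2, Rhob, Ier5 and Fosl2, were not. Ier3 lay above the Cre minus mean by 5.38 in Cre plus A, 0.90 in Cre plus B and 4.44 in Cre plus C, and Egr1 by 3.16 in A and 3.05 in C, with -0.03 in B, whereas Jun lay above it by 0.76, 0.89 and 0.93 and Btg2 by 0.93, 0.94 and 2.57. Less excision of Socs3 in Cre plus B would leave more Socs3 there, and its value differed from the lower of A and C by -0.75 on the brightest probe set and -0.23 on the next. The SD of the 3 Cre minus arrays was 0.11 on the brightest and 0.36 on the next, so Socs3 was higher in B on neither, which less excision would need, but lower beyond this spread on the brightest alone. The mean of the STAT3 targets was lowest in B (0.56 against 0.85 in A and 0.67 in C), while Tifa in B, at 1.90, lay between A and C (2.08 and 1.803), so less excision cannot be told apart from other causes. RNA quality could differ, and Cre plus B lay outside the range of A and C in 1 of the 2 control genes with probe sets at both ends of the transcript (Actb, with a 3′ minus 5′ difference of 1.35 in B against 1.29 and 1.27) and inside it for Gapdh (-0.28 against -0.30 and -0.22). That decides nothing, since an array often lies outside the range of 2 others by chance, and the Actb value in B was close to the 1.33 to 1.34 of Cre minus, so RNA quality cannot be told apart from other causes. The labels used here record no handling time, and tissue handling was not tested.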
